A study of Mus musculus with 2 samples.

How the data were processed

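Single-cell 3' libraries were made with the 10x Chromium system from sorted splenic Tregs, 1 library of 2 pooled spleens per group, per the labels' protocols. The deposited matrices hold UMI counts per gene and barcode with no normalization, made with Cell Ranger 6.0.0 per the file headers, and mm10 is the genome build per the submitters' processing notes. The annotation used for counting is not given in the sources used here. Both matrices list the same 32285 genes. Which exons of Il2ra are deleted is not given in the sources used here. Gene positions were taken from the GENCODE mouse release 21 annotation, which is on the same build.

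Groups, gene lists, markers, the rule for named genes and the alternatives were chosen before the data were examined. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Of the barcodes, 510 (7.70%) in CD25WT and 578 (7.68%) in CD25KO failed. Scrublet (Scanpy 1.11.5), run per library with an expected rate of 0.8% per 1000 barcodes, called 0 and 1 doublets. So few calls were taken as a failure of the caller, whose score distribution was not examined, and doublets are taken to remain in the main values. As an alternative chosen after seeing the data, the cells of highest doublet score were removed at the expected rate (345 and 449 cells).

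Both libraries were clustered together from log-transformed counts per 10000, with 2000 highly variable genes, 30 principal components, a shared-neighbour graph of 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. Il2ra, T cell receptor and immunoglobulin segments, ribosomal protein, mitochondrial, haemoglobin, Xist and Y-linked genes were left out of the features. Clusters were named "-like" from the fixed markers. A class needed a mean log2 fold of its markers of at least 0.25, at least 3 detected markers, and at least 2 of its own markers among the 10 leading genes, 3 among the 20 leading genes or 1 among the 3 leading genes, with no other class having more. Lineages other than CD4 T cells needed 2 of their own markers among the 10 leading genes in every case. Classes within 0.5 of the best score were told apart by their markers among the leading genes. Clusters of another lineage were left out of the T cells. This naming rule and its thresholds were set after seeing the data and revised 3 times, with the clusters and the class shares under other clusterings in view. Clusters it left unnamed held 25.1% of CD25WT and 25.0% of CD25KO T cells.

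UMIs were summed over the kept T cells of each library and scaled to counts per 1000000 UMIs (CPM) with all genes in the total. The log2 ratio is CD25KO over CD25WT. Sums have exact Poisson intervals, ratios the exact conditional interval and shares the Clopper-Pearson interval, all at 95% and all for counting error only, since cells are not replicates. Genes were counted by size of ratio among those with a mean of at least 10 CPM. For each of 25 lists, the median log2 ratio of members with a mean of at least 5 CPM was set against 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is not a test of the genotype. Ratios within classes used classes with at least 100 cells in both libraries. Standardised ratios weighted each class by its share of CD25WT cells in both libraries.

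The genes named are the 12 with the largest log2 ratio in each direction among genes with a mean of at least 20 CPM that had the same direction in every class with at least 100 cells in both libraries. Il2ra, segments, mitochondrial, ribosomal protein, haemoglobin, Xist, Y-linked and unnamed gene models were left out of that ranking. Up to 4 members of each list with the largest absolute ratio, and Foxp3, Il2rb and Il2rg, were named besides. Some genes that this rule takes are not reported here. Genes named outside this rule in the closing section were chosen after their values were seen.

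The ratio and list steps were tested on simulated data. With Poisson sums for the 7125 genes at the real depths and 200 genes set 1.5, 2 or 4 times apart, the median error of the log2 ratio was 0.05, 0.04 and 0.03, and 0 of 6925 unchanged genes came out 2-fold apart. This simulation holds counting error alone and not variation between animals. Of 40 random lists of 15 genes, 4 fell outside the central 95% with no shift, and 40 of 40 did with a shift of 1 on the log2 scale.

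Alternatives were median-of-ratios factors, TMM factors (edgeR 4.0.16), a total without ribosomal protein and mitochondrial genes, equal weight per cell, cells thinned to 2000 UMIs (leaving out 90 CD25WT and 375 CD25KO cells), other gene minimums and other cell filters. Cells of other lineages were put in, the cycling class was taken out, and cells were limited to those with a Foxp3 UMI (965 and 687 cells) or to CD25WT cells with no Il2ra UMI (3908 cells). Clustering was repeated at other resolutions and numbers of components, without cell cycle genes and after Seurat 5.3.0 integration. Added after seeing the data were clustering of thinned cells, clustering without genes apart in every class, class shares with CD25WT cells that lack an Il2ra UMI, the removal of high doublet scores, and the IL-2 and STAT5 list within single central-like clusters. A second standardisation, with UMI shares as weights and unnamed clusters apart, was not planned and was run first by oversight. The weights were then set back to those chosen beforehand, and both results are given.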

Results

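Regulatory T cells (Tregs), the CD4 T cells that hold back immune responses under the transcription factor Foxp3, were profiled by single-cell RNA sequencing from mouse spleen. The CD25WT library held Tregs with intact CD25, the alpha chain of the interleukin-2 (IL-2) receptor encoded by Il2ra. The CD25KO library came from mice with floxed CD25 alleles and the same reporters, in which tamoxifen switches on a Cre recombinase made by Foxp3-expressing cells. Tamoxifen was given at 2 mg/kg for 5 days, spleens were taken 10 days after induction, and 2 spleens were pooled per library. Both libraries were sorted on viability, CD4, GFP and tdTomato, and the CD25KO cells were in addition gated on low CD25. Each group was 1 library, so there were no replicates, no difference was tested, and every interval given covers counting error only.

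The CD25WT matrix held 6620 barcodes and 36971834 unique molecular identifiers (UMIs), and the CD25KO matrix 7530 barcodes and 36986849 UMIs. After filtering, 6110 CD25WT cells with a median of 5229 UMIs and 6952 CD25KO cells with a median of 4150 UMIs were kept. Of these, 6013 and 6863 cells were taken as T cells and hold 34872559 and 35255054 UMIs. A B-like cluster made up 1.11% (95% Clopper-Pearson interval 0.865 to 1.41) of kept CD25WT cells and 1.04% (0.811 to 1.30) of kept CD25KO cells. An erythroid-like cluster made up 0.475% (0.318 to 0.681) and 0.245% (0.143 to 0.391). Ribosomal protein genes took 39.5% of T cell UMIs in CD25WT and 31.1% in CD25KO.

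Il2ra, the targeted gene (chromosome 2, 11642807 to 11693193 on mm10), was measured at 126 CPM (UMIs scaled to a common library total) in CD25WT and 32.7 CPM in CD25KO. The log2 ratio of CD25KO over CD25WT was -1.95 (-2.04 to -1.85), from 4394 and 1151 UMIs. It was lower in the CD25KO library in each class described below, from -2.11 (-2.44 to -1.80) in central-like cells to -0.43 (-0.75 to -0.10) in effector-like cells. The signalling chains of the receptor were close in the 2 libraries, at a log2 ratio of 0.14 (0.09 to 0.19) for Il2rb and 0.25 (0.21 to 0.29) for Il2rg, against a median of 0.21 over all genes. Foxp3 was low in both, at 34.5 CPM in CD25WT and 21.8 CPM in CD25KO, a log2 ratio of -0.67 (-0.80 to -0.53). By class, the Foxp3 ratio was below 0 beyond its counting interval in central-like (-0.70), interferon-response-like (-1.57, from 7 CD25KO UMIs) and unnamed cells (-0.69). The interval crossed 0 in effector-like (0.09), follicular regulatory-like (-0.37), cycling-like (0.44) and recently stimulated-like cells (-0.08). Because 3' tags outside the deleted part check nothing, and the sort itself acts on the product of Il2ra, the Il2ra value is not a check of the deletion. Il2rb is below 0 with median-of-ratios (-0.09) or TMM factors from the trimmed mean of M values (-0.09), with ribosomal protein and mitochondrial genes out of the total (-0.06) and after standardising to the CD25WT class shares (-0.32).

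The question raised by the series title is how IL-2 receptor signalling bears on the mix of Treg subsets. Central-like cells, named from homing and quiescence genes such as Ccr7 and Igfbp4, were 49.5% (48.2 to 50.8) of CD25WT T cells and 8.22% (7.58 to 8.89) of CD25KO T cells. Effector-like cells, named from genes such as Klrg1 and S100a4, were 8.27% (7.58 to 8.99) and 33.0% (31.9 to 34.1). Follicular regulatory-like cells, named from genes such as Sostdc1 and Tox2, were 7.77% (7.10 to 8.47) and 21.5% (20.5 to 22.5). Cycling-like cells were 1.41% (1.13 to 1.75) and 3.31% (2.90 to 3.76). Recently stimulated-like cells were 5.60% (5.04 to 6.22) and 7.21% (6.61 to 7.85), and interferon-response-like cells 2.39% (2.02 to 2.81) and 1.76% (1.47 to 2.10). Unnamed clusters held 25.1% (24.0 to 26.2) and 25.0% (24.0 to 26.1).

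The gate on low CD25 was applied to the CD25KO library alone and can set these shares. The CD25KO cells were also shallower. Of the central-like cells, 1540, 1032 and 404 CD25WT cells and 415, 48 and 101 CD25KO cells lay in 3 clusters, the second of which was 95.6% CD25WT. Of the effector-like cells, 370 and 127 CD25WT cells and 1137 and 1126 CD25KO cells lay in 2 clusters, the second of which was 89.9% CD25KO. A cluster mostly of 1 library may be that library and not a cell type. With the anchor integration of Seurat the effector-like shares were 5.45% and 20.8% and the follicular regulatory-like shares 1.81% and 3.41%. With no cell filter these were 6.92% and 16.5%, and 1.60% and 4.05%, and with a stricter one 6.48% and 21.1%, and 4.48% and 28.1%. The unnamed shares rose to 45.3% and 50.1% with the integration and to 46.1% and 55.2% with no cell filter, so more cells had no name there. With the highest doublet scores removed, a choice made after seeing the data, central-like shares were 31.7% and 7.25% and follicular regulatory-like shares 6.47% and 14.9%. At 1.5 times the resolution the follicular regulatory-like shares were 1.81% and 5.00%. Recently stimulated-like shares were 13.4% and 29.4% at the lower resolution, their difference was between 5.12 and 6.51 points under 6 other settings, and the order of the libraries turned with 50 principal components (0.715% and 0.393%). Cycling-like shares were 1.43% and 5.12% under a stricter cell filter. Interferon-response-like shares were 4.74% and 2.78% with 15 principal components, and the order turned under a stricter cell filter (3.33% and 4.68%).

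**Figure D1:**
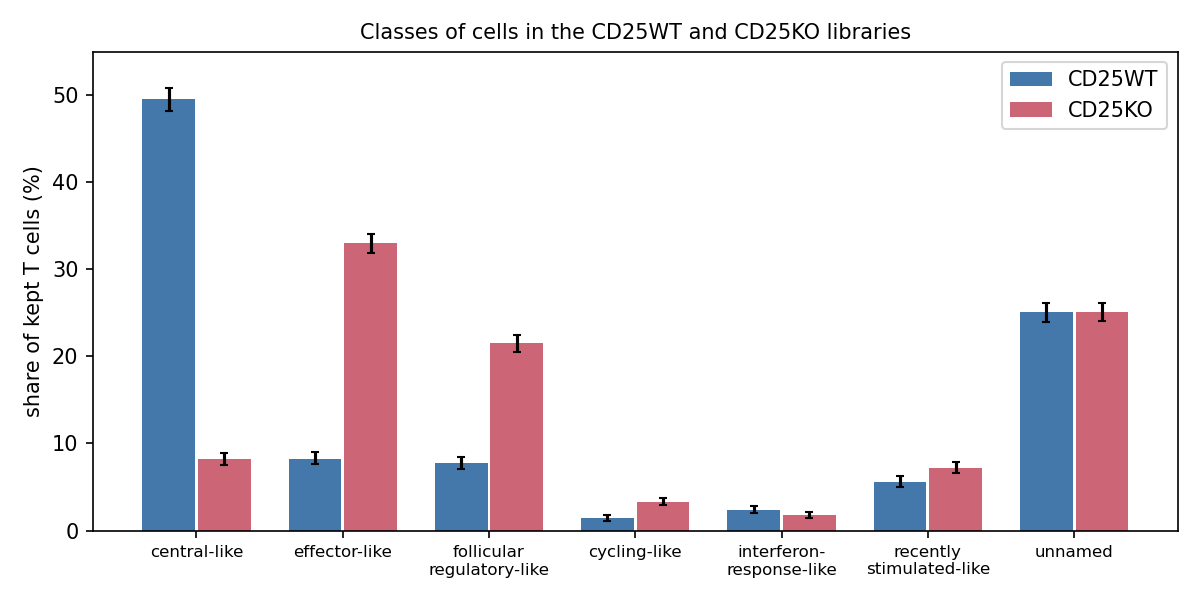
Share of kept T cells (percent, vertical axis) in each named class and in unnamed clusters, for CD25WT and CD25KO, with exact 95% Clopper-Pearson intervals as error bars. Central-like cells were 49.5% of CD25WT and 8.22% of CD25KO T cells.

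Ccl5, a chemokine gene, had the highest ratio among genes of 1 direction in every class. It was at 33.6 CPM in CD25WT and 257 CPM in CD25KO, a log2 ratio of 2.94 (2.85 to 3.03). Il1r2, a decoy receptor for IL-1, stood at 2.61 (2.45 to 2.77), the interferon-induced Ifitm2 at 2.41 (2.26 to 2.56) and the calcium-binding S100a6 at 2.34 (2.30 to 2.38). The chemokine gene Cxcl10 had a log2 ratio of 2.21, Ube2m, which conjugates NEDD8, 2.00, the invariant chain gene Cd74 1.98 and the enkephalin precursor gene Penk 1.93. Serpina3g (1.90), Pglyrp1 (1.88), S100a4 (1.87) and Tox2 (1.86) completed the 12 largest. After standardising to the CD25WT class shares, Ccl5 stood at 1.32, Il1r2 at 1.64, Ifitm2 at 1.12, S100a6 at 0.52, Penk at 1.08, Serpina3g at 0.92, Pglyrp1 at 0.89, S100a4 at 0.09 and Tox2 at 0.60, and Cd74 was at 0.996 with cells of other lineages put in.

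Igfbp4, which encodes an insulin-like growth factor binding protein, was the gene with the lowest ratio, at 119 CPM in CD25WT and 12.1 CPM in CD25KO, a log2 ratio of -3.29 (-3.44 to -3.15). Mtmr9 followed at -2.71 (-2.88 to -2.55), the AP-1 subunit gene Jun at -1.73 (-1.88 to -1.58) and the glutathione transferase gene Gstp1 at -1.66 (-1.79 to -1.53). Ecm1 (-1.54), the Treg receptor gene Gpr83 (-1.49), the stress-induced Sesn1 (-1.43) and Tsc22d3, a glucocorticoid target (-1.39), were lower as well. So were Igf2r (-1.34), the lymph node homing receptor gene Ccr7 (-1.13) and Ddit4, an inhibitor of mTORC1 (-1.10). Standardised in the same way, Igfbp4 stood at -0.85, Jun at -1.07, Ecm1 at -0.89, Gpr83 at -0.95, Tsc22d3 at -0.86, Igf2r at -0.55 and Ccr7 at -0.11. Igfbp4 and Gstp1 have a near-identical stretch in another gene's transcript, so that their reads may be shared and their values are uncertain. Such matches are given only for genes at least 1.5-fold apart in the same direction in every class, so the other genes named are not cleared. Il1r2, S100a6, S100a4, Tox2, Igfbp4 and Ccr7 are also among the markers used to name classes. The counting interval of the ratio crossed 0 in at least 1 class for Ifitm2, S100a6, Penk, Serpina3g, Tox2, Mtmr9, Ecm1 and Ccr7, and the central-like ratios of Il1r2 and Tox2 rest on 3 CD25KO UMIs each.

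Among 7125 genes with a mean of at least 10 CPM, 261 were at least 2-fold higher and 40 at least 2-fold lower in CD25KO, and 752 and 106 at least 1.5-fold. These counts describe the size of differences between 2 libraries and not tested changes. The median log2 ratio of these genes was 0.21, and ratios are to be read against that shift. Of the genes 2-fold apart, 86.7% were higher in CD25KO. That share was 69.1% with median-of-ratios factors, 69.0% with TMM factors, 72.7% with ribosomal protein and mitochondrial genes out of the total and 66.7% after standardising to the CD25WT class shares. Standardising left 36 genes at least 2-fold higher and 18 at least 2-fold lower. Its weights do not reach inside a class, and all unnamed clusters counted as 1 class. Of these, 1 held 10.1% of CD25WT and 19.0% of CD25KO T cells and another 14.0% and 5.83%. Clusters inside the central-like and effector-like classes were filled unequally too, so differences in mix remain in standardised values.

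**Figure D2:**
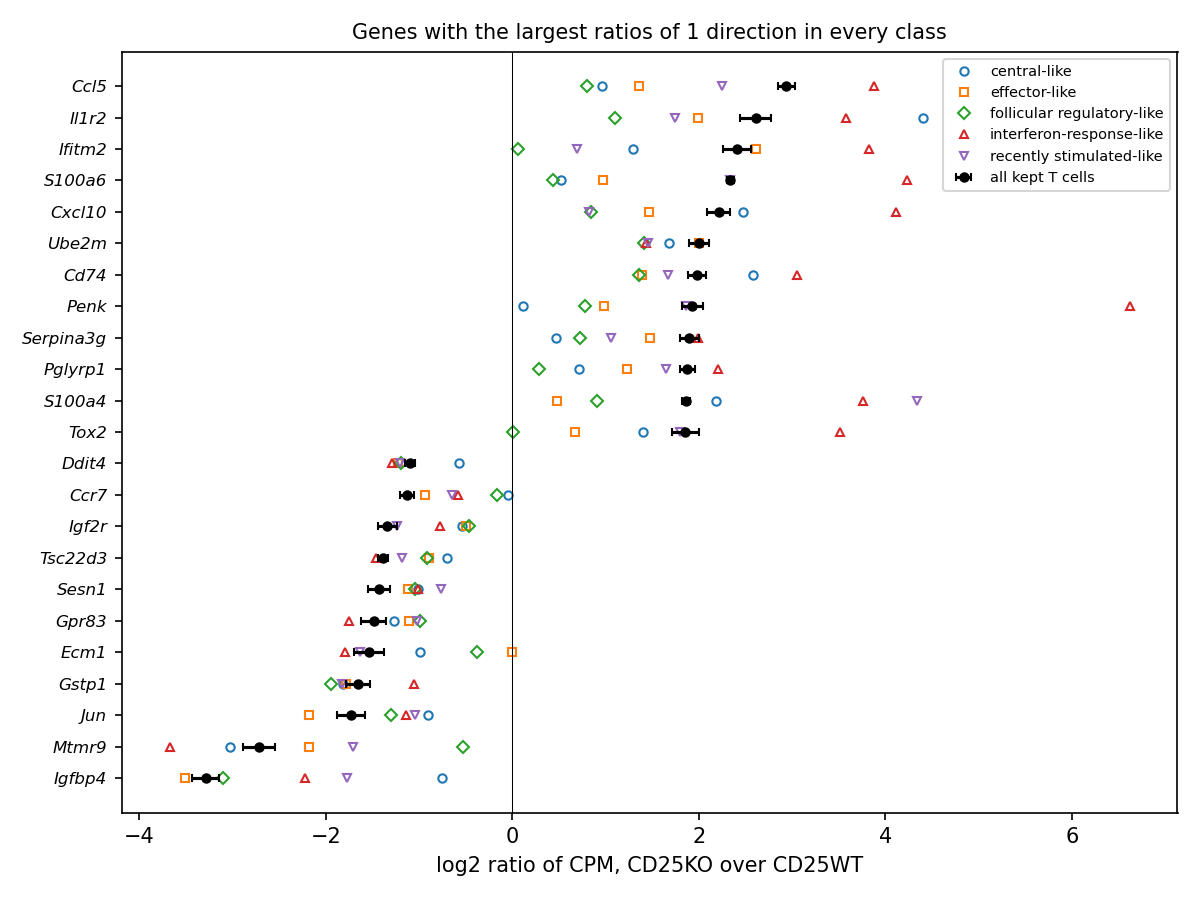
Log2 ratio of CPM, CD25KO over CD25WT (horizontal axis), for 12 of the genes with the largest ratios above 0 and 11 of those below 0, over all kept T cells with 95% counting intervals (filled) and within each class with at least 100 cells in both libraries (open). Ratios run from -3.29 for Igfbp4 to 2.94 for Ccl5.

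All 16 effector Treg genes measured were at least 1.5-fold higher in CD25KO, with a median log2 ratio of 1.67 (percentile 100 among matched random lists). Gzmb, the gene of the protease granzyme B, stood at 4.84 (4.43 to 5.28), from 49 UMIs in CD25WT and 1422 in CD25KO, and the inhibitory receptor gene Klrg1 at 4.10 (3.60 to 4.66). All 6 genes measured of the tissue-type Treg list marked by the IL-33 receptor ST2 were at least 1.5-fold higher, with a median of 1.61 (percentile 100), among them Areg (2.96) and Il1rl1, which encodes ST2 (2.15). Of 9 follicular regulatory genes, 7 were at least 1.5-fold higher, with a median of 1.05 (percentile 100), such as Sostdc1 (1.75) and Pdcd1, the gene of PD-1 (1.37). Of 10 central Treg genes, 8 were at least 1.5-fold lower, with a median of -1.05 (percentile 0), among them the survival gene Bcl2 (-1.33). In cells with a Foxp3 UMI the ST2 tissue-type median was 2.54 and the follicular regulatory median 1.67. These lists share markers with the class names and are no independent measure of the class shares.

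Of 10 suppressive molecules, 6 were at least 1.5-fold higher in CD25KO and none was as much lower, with a median of 1.70 (percentile 100). Fgl2 (2.78) and the inhibitory receptor gene Tigit (2.21) were among them. The Treg identity list of 17 genes had a median of 0.49 (percentile 99.99), which was 0.05 after standardising to the CD25WT class shares and -0.09 under an unplanned standardisation that was run first by oversight, with 8 genes at least 1.5-fold higher, such as the integrin gene Itgae (1.54), and 3 as much lower, which were Foxp3 (-0.67), Gpr83 (-1.49) and Lrrc32, the gene of the TGF-beta docking receptor GARP (-1.56). Of 18 IL-2 and STAT5 responsive genes, 5 were at least 1.5-fold lower and 3 higher, with a median of -0.12 (percentile 0). Myc (-1.41) and Lrrc32 were among the lower, and Prdm1, the gene of Blimp-1 (1.83), and Il1rl1 among the higher. This median was 0.0032 when CD25WT cells with an Il2ra UMI were left out. The 7 IL-2 receptor chain and proximal signalling genes had a median of 0.14 (percentile 27.6) and, through Il2ra, a mean of -0.10. With TMM factors that median was -0.09, the IL-2 and STAT5 median -0.36 and the Treg identity median 0.25. Jak3 stood at 0.34 and Stat5a at 0.33. Standardised to the CD25WT class shares, the medians were 0.30 for the effector, 0.42 for the ST2 tissue-type, 0.25 for the suppressive, 0.38 for the follicular regulatory and -0.17 for the central list.

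Of 25 cell cycle genes, 19 were at least 1.5-fold higher, with a median of 1.24 (percentile 100), such as the cyclin gene Ccnb1 (2.47) and Ube2c (2.32). Without the cycling class the median was 0.41, and with cells thinned to the same depth 0.71. Of 14 T cell receptor activation genes, 8 were at least 1.5-fold higher and 2 lower, with a median of 0.70 (percentile 100), among them Egr2 (1.23) and Irf4 (1.02). The 13 genes of the T cell receptor complex had a median of 0.32 (percentile 96.1), with Zap70 at 0.69 and Cd4 at 0.52. Of 8 helper lineage genes measured, 6 were at least 1.5-fold higher, with a median of 1.14 (percentile 100), such as Il4 (2.34) and Tbx21, the gene of T-bet (2.07). Trafficking receptors had a median of 0.65 over 20 genes (percentile 100), with 11 at least 1.5-fold higher, such as Cxcr6 (2.42) and Cxcr3 (1.66), and 3 lower. Of 16 apoptosis regulators, 6 were at least 1.5-fold higher and 2 lower, with a median of 0.49 (percentile 99.98). After standardising to the CD25WT class shares, the medians were 0.06 for the cell cycle, 0.23 for the T cell receptor activation, 0.13 for the T cell receptor complex, 0.30 for the helper lineage, -0.11 for the trafficking and 0.21 for the apoptosis list. With TMM factors the T cell receptor complex stood at 0.09, T cell receptor activation at 0.47, trafficking at 0.42 and apoptosis at 0.26.

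Medians of the other cytokine receptor, interferon, metabolic and stress lists lay between -0.19 and 0.35. The 12 other common-gamma and related cytokine receptors had a median of -0.05 (percentile 0.09), with Il18r1 at 1.07 (-0.19 after standardising to the CD25WT class shares) and Il4ra at -1.07, and this median was above 0 with each cell weighed the same (0.05) and -0.28 with TMM factors. Interferon response genes had a median of 0.04 over 20 genes (percentile 0.26), which was below 0 with TMM factors (-0.19). Within each class measured this median was above 0, from 0.10 (percentile 84.3) in effector-like to 0.26 (percentile 98.7) in interferon-response-like cells. Over all T cells Ifi27l2a stood at 0.68 and Usp18 at -0.54 (0.22 after standardising). Glycolysis genes had a median of 0.35 over 13 genes (percentile 97.3), with Tpi1 at 1.01 and Eno1 at -0.52, and oxidative phosphorylation genes 0.27 over 22 genes (percentile 95.2), with Cox8a at 0.54. With TMM factors these medians were 0.12 and 0.03, and after standardising -0.04 and 0.01. Cholesterol synthesis genes had a median of -0.19 over 14 genes (percentile 0), which was -0.42 with TMM factors. The median of 13 dissociation stress genes was 0.02 (percentile 1.22), with Junb at 0.68, and was below 0 with TMM factors (-0.21).

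Markers of other cell types also differed between the libraries. The 4 cytotoxic and natural killer receptor genes measured had a median of 3.52 (percentile 100) and include Gzmb, Klrg1, Ccl5 and Nkg7 (2.10), of which Gzmb and Klrg1 also belong to the effector list. The 3 CD8 T cell genes measured had a median of 2.10 (percentile 99.99) that rests on Ccl5 and Nkg7, while Cd8b1 itself stood at 0.25. The 3 B cell genes measured had a median of 0.84 (percentile 99.3), with Cd74 at 1.98, Ighm at 0.84 and Cd79b at 0.65. After standardising, the cytotoxic median was 1.01, the CD8 T cell median 0.69 and the B cell median 0.35, and with no CPM minimum the cytotoxic median was 2.10 and the CD8 T cell median 1.10. Of the myeloid list 1 gene, Cst3 (0.43, and -0.01 after standardising), was measured. The 4 erythroid genes measured had a median of -0.90 (percentile 0), with Hbb-bs at 117 CPM in CD25WT and 62.6 CPM in CD25KO. The erythroid median was -1.78 with no cell filter and -0.45 in cells with a Foxp3 UMI.

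**Figure D3:**
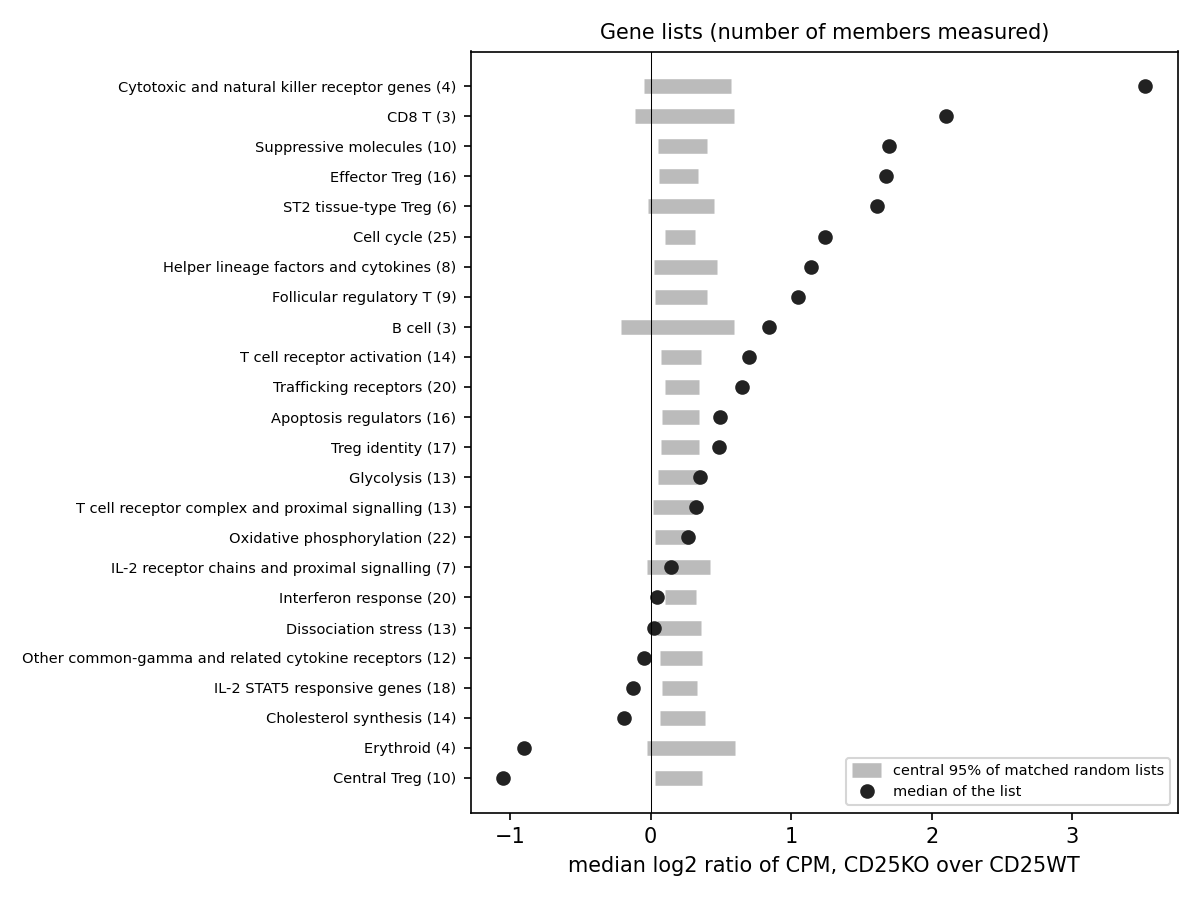
Median log2 ratio of CPM, CD25KO over CD25WT (horizontal axis), of each gene list with at least 3 measured members (points), beside the central 95% of 10000 random lists matched on expression (grey bars). The effector Treg list lies at 1.67 and the central Treg list at -1.05.

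The median lay nearer 0 than over all T cells for 16 of 23 lists in central-like, 20 of 24 in effector-like, 20 of 23 in follicular regulatory-like and 20 of 24 in recently stimulated-like cells, but for 11 of 24 in interferon-response-like cells. Among central-like cells, the IL-2 and STAT5 responsive genes had a median of -0.58 (percentile 0) and the Treg identity list -0.55 (percentile 0). The Treg identity list stood at 0.46 in effector-like, 0.07 in follicular regulatory-like, 0.38 in interferon-response-like and 0.41 in recently stimulated-like cells. The suppressive list was below 0 in central-like cells, at -0.36 over 5 genes (percentile 0.155). It stood at 0.84 in effector-like, 0.09 in follicular regulatory-like, 2.90 in interferon-response-like and 0.87 in recently stimulated-like cells. The erythroid median was lowest in central-like cells, at -1.82 (percentile 0). In the 3 central-like clusters, in the order given with the shares, the IL-2 and STAT5 median was -0.03 (percentile 10.2), -0.62 (percentile 0) and -0.95 (percentile 0). Il2ra and the list members Lrrc32, Myc and Bcl2 are among the 10 leading genes of the second cluster, which is 95.6% CD25WT. Over all central-like cells Lrrc32 was at -2.22, Myc at -1.50 and Il2rb at -0.82 (-1.01 to -0.63). The effector list stood at 0.55 (percentile 99.95) in central-like cells and 0.78 (percentile 100) in effector-like cells, where Gzmb was at 3.78 and Fgl2 at 2.02. In follicular regulatory-like cells the IL-2 and STAT5 list had a median of 0.16 (percentile 98.8), the follicular regulatory list -0.14 (percentile 0.945) and Sostdc1 a log2 ratio of 0.06. In recently stimulated-like cells the effector list stood at 0.96 (percentile 100), and in interferon-response-like cells at 1.80 (percentile 100). The central list stood at -0.57 and -0.77 in these classes (percentile 0 in both). The mix of cells inside each may therefore differ between the libraries, which was not tested. Some interferon-response-like values rest on few UMIs in CD25WT and CD25KO, such as 11 and 100 for S100a4 and 1 and 5 for Gzmb. The central-like and effector-like values compare cells from clusters that the 2 libraries fill unequally, as given with the shares.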

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

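Choices added after seeing the data were the removal of high doublet scores, thinning or leaving out genes apart in every class before clustering, and shares without CD25WT cells that hold an Il2ra UMI. Standardising by UMI shares was likewise unplanned and was run first by oversight. The central-like share was lower and the effector-like share higher in CD25KO under every clustering run, and the follicular regulatory-like share was higher in each that named the class (the lower resolution named no such class, nor a cycling one). Among the list medians, gene counts, Il2ra and class shares, 360 alternative values stayed within their spread, 123 moved beyond it with the same sign and 25 changed sign. Among single named genes the numbers were 757, 715 and 12, of which Il2rb made 5 and Usp18 2. Both tallies include the setting that kept the doublet calls. It left the gene counts and class shares as they were, so its values stayed the same by construction. Some list members that kept their sign became small: under 1 alternative or another Itgae was 0.15, Sostdc1 0.21, Pdcd1 0.24, Tpi1 0.09, Cxcr3 0.33 and Il4ra -0.20. Median-of-ratios factors, TMM factors and a total without ribosomal protein and mitochondrial genes each move every log2 ratio by 1 constant. The median over genes with a mean of at least 10 CPM went from 0.21 to -0.02, -0.02 and 0.02. The order of the genes is therefore unchanged, though genes may cross a CPM minimum. For the other settings the cause was not tested except where the setting itself removes the cells or genes concerned. With 1 library per group, depth limits only the counting error, and no setting can stand in for replicates.

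With median-of-ratios factors, 152 genes were 2-fold higher and 68 lower in CD25KO, and Il2ra stood at -2.18. The list medians that moved were IL-2 receptor chains -0.088, interferon response -0.19, T cell receptor activation 0.47, T cell receptor complex 0.089, glycolysis 0.12, oxidative phosphorylation 0.036, cholesterol synthesis -0.42, dissociation stress -0.21 and erythroid -1.13. TMM factors gave 151 and 68 genes, Il2ra -2.18, and medians of -0.091, -0.19, 0.47, 0.086, 0.12, 0.033, -0.42, -0.21 and -1.13 for the same lists. Without ribosomal protein and mitochondrial genes in the total, 88 genes were 2-fold lower, Il2ra was -2.14, and these medians were -0.054, -0.15, 0.42, 0.12, 0.16, 0.070, -0.39, -0.18 and -1.10.

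Weighing each cell the same gave Il2ra -1.67, other cytokine receptors 0.048, cell cycle 0.75, oxidative phosphorylation 0.17, dissociation stress -0.0072 and erythroid -0.73. Thinned cells gave -1.72, 0.094, 0.71, 0.16, -0.062 and -0.69 for the same. Without the cycling class the cell cycle median was 0.41. In cells with a Foxp3 UMI, 434 genes were 2-fold higher and 65 lower, and medians were other cytokine receptors 0.014, effector 2.26, ST2 tissue-type 2.54, cell cycle 1.86, oxidative phosphorylation 0.41 and erythroid -0.45. Without CD25WT cells that hold an Il2ra UMI, the IL-2 and STAT5 median was 0.0032, other cytokine receptors 0.074, dissociation stress -0.037 and erythroid -0.81. The erythroid median was -1.78 with no cell filter and -1.26 with the stricter one. With no CPM minimum, 2093 genes were 2-fold higher and 849 lower and the cytotoxic median was 2.10. With a minimum of 50 CPM the counts were 69 and 14.

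Standardised to the CD25WT class shares, 36 genes were 2-fold higher and 18 lower, and Il2ra was -1.74. Medians were suppressive 0.25, central -0.17, effector 0.30, ST2 tissue-type 0.42, follicular regulatory 0.38, cell cycle 0.065, T cell receptor activation 0.23, T cell receptor complex 0.13, helper lineage 0.30, trafficking -0.11, glycolysis -0.040, oxidative phosphorylation 0.011, dissociation stress -0.17, cytotoxic 1.01, CD8 T 0.69 and erythroid -1.03. Il18r1 (-0.19), Ccr2 (-0.073), Pgam1 (-0.0034), Cst3 (-0.011), Usp18 (0.22) and Il2rb (-0.32) changed sign. Standardising by UMI shares gave 35 and 18 genes and Il2ra -1.71. It gave Treg identity -0.095, against 0.053 under the standardisation chosen beforehand, which differs in both the weights and the unnamed clusters, suppressive 0.45, central -0.16, effector 0.41, ST2 tissue-type 0.46, follicular regulatory 0.30 and cell cycle 0.12. T cell receptor activation was 0.28, T cell receptor complex 0.12, trafficking 0.028, glycolysis -0.061, oxidative phosphorylation 0.037, dissociation stress -0.15, cytotoxic 1.04, CD8 T 0.74 and erythroid -1.18.

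Differences in share are CD25KO minus CD25WT, in percentage points, against main values of -41.3 for central-like, 24.7 for effector-like and 13.7 for follicular regulatory-like cells. In that order they were -28.1, 9.60 and 2.45 with no cell filter, -39.6, 14.6 and 23.6 with the stricter filter, -28.1, 15.3 and 1.60 with Seurat integration, -24.5, 18.8 and 8.39 without high doublet scores, -44.1, 19.4 and 11.4 after thinning, and -36.6, 21.9 and 10.4 without CD25WT cells that hold an Il2ra UMI. Central-like and effector-like differences were -44.1 and 19.6 at the lower resolution. Central-like and follicular regulatory-like differences were -39.7 and 3.19 at 1.5 times the resolution, -44.6 and 11.7 with 50 components, and -43.8 and 9.12 without genes apart in every class. With 15 components effector-like and follicular regulatory-like differences were 19.98 and 10.05. Recently stimulated-like differences were 6.02 with no filter, 16.0 and 5.26 at the lower and higher resolution, 5.31 and -0.32 with 15 and 50 components, 5.52 with integration, 6.51 without high doublet scores and 5.12 without genes apart in every class. Interferon-response-like differences were 1.34 with the stricter filter, -1.43 at the higher resolution, -1.96 with 15 components, -1.33 without cell cycle genes, -1.38 without high doublet scores and -1.50 without genes apart in every class. The cycling-like difference was 3.69 with the stricter filter.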

Other observations

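Among the 3 unnamed T cell clusters, the one led by Jchain and Naip5 held 10.1% of CD25WT and 19.0% of CD25KO T cells. Its best match by score was plasma cells, through Jchain, and the naming rule kept it among the T cells. Jchain stood at 52.0 CPM in this cluster against 0.949 CPM in other T cells. A Jchain UMI was found in only 0.262% of its cells against 0.319% of other T cells, so few cells carry that signal. The T cell gene Cd3e stood at 783 CPM against 780 CPM. The one led by Gbp2b and Prg4 held 14.0% and 5.83%, and a small one led by Tmem176b and Tmem176a held 0.948% and 0.219%. Of 4823 genes, 40 were at least 1.5-fold apart in the same direction in each of the 5 classes with enough cells, 32 of them higher and 8 lower in CD25KO. Besides genes already named they include the RNA-binding protein gene Hnrnpd (1.60), the mRNA export factor gene Alyref (1.44), the deubiquitinase gene Otulin (1.11) and Erh (-0.66). These genes were chosen after their values were seen.

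The tests of the sort gate and of doublets on class shares, the test of the smaller central-like clusters, the comparisons of CD25KO with CD25WT cells lacking an Il2ra UMI, and the choice of the 40 genes, came after the results they bear on had been seen. The other tests were written before their results. The first pattern is the lower share of central-like and higher share of effector-like and follicular regulatory-like cells in CD25KO. The lower depth of CD25KO cells is argued against for the central-like difference, which was -44.1 points after thinning, against a main value of -41.3. The effector-like and follicular regulatory-like differences were 19.4 and 11.4 points after thinning, against 24.7 and 13.7, so depth may account for part of these. Thinning also raised the unnamed share, from 25.1% to 28.3% in CD25WT and from 25.0% to 38.6% in CD25KO. Doublets stay open: with the highest scores removed the central-like difference was -24.5 points, but the scores come from a caller with 0 and 1 calls and the unnamed share of CD25WT rose from 25.1% to 44.8%. The gate on low CD25 stays open: among CD25WT cells the log2 ratio of Il2ra over the other cells was 0.52 (0.43 to 0.61) in central-like, -1.70 (-2.00 to -1.43) in effector-like and -2.58 (-3.00 to -2.19) in follicular regulatory-like cells, so that such a gate may lower the first share and raise the others with no effect of the deletion. Yet CD25WT Il2ra was alike in central-like (149 CPM), interferon-response-like (147 CPM) and unnamed cells (147 CPM). The interferon-response-like shares were 2.39% and 1.76%, and the unnamed shares, which pool clusters that moved in opposite directions, 25.1% and 25.0%. Il2ra RNA thus does not single out the central-like class, and protein was not measured here. Leaving out CD25WT cells with an Il2ra UMI left a central-like difference of -36.6 points, but a missing UMI is a weak stand-in for low protein. Loss of CD25 itself is an equally open and untested explanation, because the gate was applied to 1 genotype alone.

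The second pattern is the lower median of IL-2 and STAT5 responsive genes in central-like CD25KO cells (-0.58). The lower depth of CD25KO cells stays open: the median in thinned cells was -0.61 (percentile 0), but these cells kept the classes given before thinning. Ratios of scaled sums over the same cells hardly depend on depth, so this value could not have shown an effect of depth on the classes. A mix of clusters inside the class is argued against as the whole of it: the median was inside the range of matched random lists in the largest cluster (-0.03, percentile 10.2) but below it in the smallest, which both libraries fill (-0.95 with 101 CD25KO cells, percentile 0). The other, 95.6% CD25WT, had -0.62 (percentile 0) but has Il2ra and 3 genes of the list among its 10 leading genes and so decides nothing. Whether the gate accounts for part stays open: CD25WT central-like cells without an Il2ra UMI had a median of -0.59 (percentile 0) against those with one. That contrast also differs in clusters, since 1153, 388 and 211 of the 1540, 1032 and 404 CD25WT cells lacked an Il2ra UMI. It cannot separate the gate from the cluster led by Il2ra and list genes. CD25KO cells against CD25WT cells without an Il2ra UMI stood at -0.29 (percentile 0) in the class. In the 3 clusters, in the order given with the shares, they stood at 0.10 (percentile 61.7), -0.30 (percentile 0.14) and -0.47 (percentile 0). The gate on protein and the loss of CD25 itself both stay open, the latter untested.

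The third pattern is the 40 genes apart in the same direction in every class, by amounts that differ between classes (Igfbp4 from -3.51 to -0.76), which may reflect the 2 sets of mice or libraries and not cell state. Of the 40, 0 lie within 20 Mb of Il2ra, so none of them is itself a gene carried along that near to the targeted locus. Random draws hold only 0.527 on average, so this count cannot show whether a strain difference was carried along there. Its effects on genes elsewhere, and strain differences elsewhere in the genome, stay open. Reads shared with near-identical transcripts stay open for part of them: 25.0% (10 of 40) have a match of at least 80 bases at 95% identity in another gene's transcript, against a median of 5% and an upper bound of 15% in random draws. Both matrices list the same genes, so sharing alone need not make the libraries differ, and how it would do so was not tested. Igfbp4, Gstp1 and Erh are among the 10 with a match, and Ube2m, Sesn1 and 28 others have no such match. No biological explanation was tested for these genes.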
